A study of Homo sapiens with 6 samples.

How the data were processed

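RNA from 6 flasks labelled as NCI-H446, an established human small cell lung cancer line, was measured on single-colour Phalanx OneArray microarrays. The identity of the line in the control flasks was taken from the labels and was not tested. Per the labels' protocols, cells were treated once they covered most of the flask, RNA was extracted with Trizol, checked for purity and integrity, amplified as amino allyl aRNA and labelled with Cy5. The group of each sample was taken from its title: 3 control flasks with 15 µl of DMSO (control 2, 5 and 6) and 3 drug flasks (drug 1, 3 and 4). The name, the dose and the exposure time of the drug are not given in the sources used here. The sample characteristics give a DMSO volume for the control flasks only, so whether the solvent was matched in the drug flasks was not established. The labels describe separate flasks of the same line, so the p-values of single probes and genes rest on the spread between flasks. The camera p-values of gene lists below compare a list with the other genes. The permutation p-values compare orders of the 6 arrays.

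The deposited values are intensities on a linear scale, 31741 probes for each of the 6 arrays. How the authors corrected the background and scaled the deposited intensities is not given in the sources used here. On each array 100% of the intensities under 500 were whole multiples of a single step, within 0.05 of a step. The step ran from 0.611 on control 2 to 1.58 on drug 1, which reads as whole scanner units times a scale factor per array. Values below zero numbered 462 on control 2, 968 on control 5 and 1 on drug 4, and 0 on the other arrays, so a background had been subtracted or shifted on at least those arrays. Array-level background, spot flags and detection calls were not used here.

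The array medians differed by 0.338 on the log2 scale, above the limit of 0.1 set before the data were examined, so the intensities were quantile normalized between arrays. Values below 0 were then set to 0, 1 was added and log2 was taken. The plan had foreseen zeros but not negative values, and the floor at 0 was added for that reason. The common distribution had a median of 8.73 and a lower quartile of 6.86. A group mean under that lower quartile is called dim below, since no background level per probe was used. A fold change is on the scale of log2(intensity + 1) and depends on the added constant for dim probes. The median within-group standard deviation was 0.196 on the log2 scale. With arrays, it is the number of arrays, 3 per group, that limits the precision.

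Probe names came from the platform annotation in GEO. Of all probes, 24740 named 1 gene, 977 named several and were not used for any gene, and 6024 named none. Symbols were updated through the synonyms of RefSeq genes on assembly GRCh38.p14, which was used only for names and for the order of neighbouring genes. Of the gene symbols, 16811 were current, 1492 were updated and 57 were kept as annotated. Each of the 18336 genes was read from its probe with the highest mean over all 6 arrays.

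Drug and control arrays were compared with limma 3.58.1 in R 4.3.3, using lmFit and eBayes without a trend, two-sided, with no covariate. P-values were adjusted with the Benjamini-Hochberg method over all 31741 probes, and a probe or gene was called changed at an adjusted p below 0.05. The 31 gene lists were written before the data were examined and were tested with camera at its preset correlation of 0.01 between genes, adjusted over the 31 lists. They covered p53 targets, G2/M and mitosis, S phase and replication, recombination and Fanconi repair, histones, ATF4 and the integrated stress response, endoplasmic reticulum chaperones, heat shock, NRF2, metallothioneins, cholesterol, fatty acid synthesis, NF-kappaB and inflammation, interferon, hypoxia and glycolysis, neuroendocrine genes, non-neuroendocrine genes, epithelial genes, the BCL2 family, immediate early genes, ribosome biogenesis, ribosomal proteins, oxidative phosphorylation, autophagy and lysosome, the proteasome, tubulins, drug transporters and targets, aryl hydrocarbon receptor targets, splicing factors, and markers of fibroblasts or endothelium and of blood cells. The lists held 704 measured members from 689 genes, 15 of which sat in more than 1 list.

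The genes named were those fixed by a rule set before the data were examined: the 12 largest rises and 12 largest falls among changed genes whose 3 drug arrays all lay on the same side of the 3 control arrays, and from each list up to 3 changed genes with the largest absolute change. This gave 111 genes. Of these, 30 had several probes, 0 of them had a changed probe of opposite sign, 5 had another probe that did not pass, and 8 had another changed probe with a fold over 1.5 times apart. RAD51C, FDPS, ACAT2, SYT1, SYP, ENO2, CHGA, DLL3, GRP, CHGB, SCG2, IRF7, OASL, IRF1 and CDKN1A lie outside the rule and were chosen after their values were seen.

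The alternatives tried were the values as deposited, median centring and cyclic loess in place of quantile normalization, 2 filters on dim probes, 50 added in place of 1, other variance models, array weights, the title number as a covariate, the mean of all probes of a gene, a stricter threshold of 0.01, a test against a minimum log2 change of 0.5, other set tests, and leaving out each array in turn. A covariate for array brightness and the removal of the 2 brightest arrays were chosen after seeing the data. The procedure was tested on simulated data with the means and spreads of the 31741 probes and 200 seeded changes. It recovered 0% of the 50 changes of 0.5, 38% of those of 1, 74% of those of 2 and 98% of those of 4 on the log2 scale, with 8 false calls. In this simulation few probes changed, which makes the adjusted threshold stricter than in the real comparison. A seeded list of 25 genes shifted by 0.5 was called, with an adjusted p of 1.46e-24 (0.0246 with an estimated correlation), along with 0 of 30 unshifted lists. The simulated probes were drawn independently, whereas the estimated correlation of the real interferon list was 0.319. The simulation therefore cannot show how often a list of correlated genes is called falsely.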

Results

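Gene expression in cells labelled as NCI-H446, a small cell lung cancer line, was compared between 3 control and 3 drug flasks. The control flasks were given DMSO, a common drug solvent, and the drug flasks an unnamed chemotherapy drug. The aim was to find which genes differ after treatment. Each flask was measured on its own array. The median intensity was 439, 376 and 394 on control 2, 5 and 6, and 421, 428 and 476 on drug 1, 3 and 4. The source names give DMSO volumes and cell line numbers that climb by 1 from row to row within a group, whereas the sample characteristics give 15 µl of DMSO for each control and NCI-H446 for all 6 samples. The latter were used.

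KIF5C, a neuronal kinesin heavy chain, rose from a log2 intensity of 4.66 ± 0.082 (SD, n = 3) in the control flasks to 10.71 ± 0.073 (n = 3) in the drug flasks. SYT11, a synaptotagmin of vesicle traffic, rose from 7.67 ± 0.17 to 12.81 ± 0.17, which is 35.4-fold, and NCAM1, the neural cell adhesion molecule, from 7.20 ± 0.16 to 12.28 ± 0.21, which is 33.7-fold on the brightest of its 3 probes and 3.98-fold and 3.06-fold on the others. The NCAM1 probe with 3.06-fold was dim in both groups, and its fold became 1.84 with 50 added in place of 1. RIN2, a regulator of RAB5 and endocytosis, fell from 14.31 ± 0.11 to 9.29 ± 0.077 (32.4-fold, and 17.1-fold on its other probe), and NNMT, which methylates nicotinamide, fell from 17.24 ± 0.070 to 12.88 ± 0.12. Genes of mitosis were lower with the drug, 28 of 30 on the list, and genes of cholesterol synthesis were higher, 16 of 21. Adjusted p-values were 5.21e-06 for KIF5C, 6.72e-06 for SYT11, RIN2 and NNMT, and 7.23e-06 for NCAM1.

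Among the 12 largest rises were also CGA, the common alpha subunit of the glycoprotein hormones (log2 fold change 5.03, SE 0.145), IFI30, a lysosomal thiol reductase of antigen processing (4.90, SE 0.125), and CKB, the brain-type creatine kinase (4.87, SE 0.154). HPCAL4, a neuronal calcium sensor, rose by 4.56 (SE 0.140), TNFSF9, a costimulatory ligand of the TNF family, by 4.51 (SE 0.202), and GBP5, an interferon-inducible guanylate-binding protein, by 4.49 (SE 0.125). RGL1, an exchange factor for Ral, rose by 4.47 (SE 0.123), LMCD1, a LIM domain protein, by 4.44 (SE 0.147), and TTC29, a protein of the sperm flagellum, by 4.43 (SE 0.165). KIF5C, HPCAL4 and GBP5 were dim in the control flasks, and with 50 added in place of 1 their folds of 66.3, 23.6 and 22.5 became 23.2, 14.4 and 9.65. The other 2 probes of GBP5, also dim in the control flasks, gave 11.8-fold and 6.46-fold, which became 6.008-fold and 3.205-fold with 50 added. With 50 added KIF5C no longer had the largest rise, and IFI30 (29.4-fold), SYT11 (28.7-fold), CKB (27.8-fold), CGA (27.0-fold) and NCAM1 (25.5-fold) came before it.

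Among the 12 largest falls, FGF2, a fibroblast growth factor, changed by -4.19 (SE 0.153) and GBP3, another guanylate-binding protein, by -4.11 (SE 0.132). IFIT3, an interferon-induced protein, changed by -4.01 (SE 0.249), and RFLNA, a filamin partner named FAM101A on the array, by -3.99 (SE 0.202). NRP1, a coreceptor for semaphorins and VEGF, changed by -3.97 (SE 0.211), AMIGO2, a membrane adhesion protein with 1 of 3 probes that did not pass, by -3.97 (SE 0.153), and SERPINH1, the collagen chaperone, by -3.93 (SE 0.115). TRABD2B changed by -3.92 (SE 0.152) but by -0.58 on its other probe, the adhesion receptor ADGRG6 by -3.90 (SE 0.167), and PAPPA, a protease that cleaves IGF-binding proteins, by -3.89 (SE 0.160). The other probes gave smaller falls for NRP1 (-1.25 and -1.82) and PAPPA (-2.07). The highest adjusted p among these 24 genes was 5.04e-05, for IFIT3, and by the rule that chose them all 3 drug arrays lay on one side of the 3 control arrays.

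**Figure D1:**
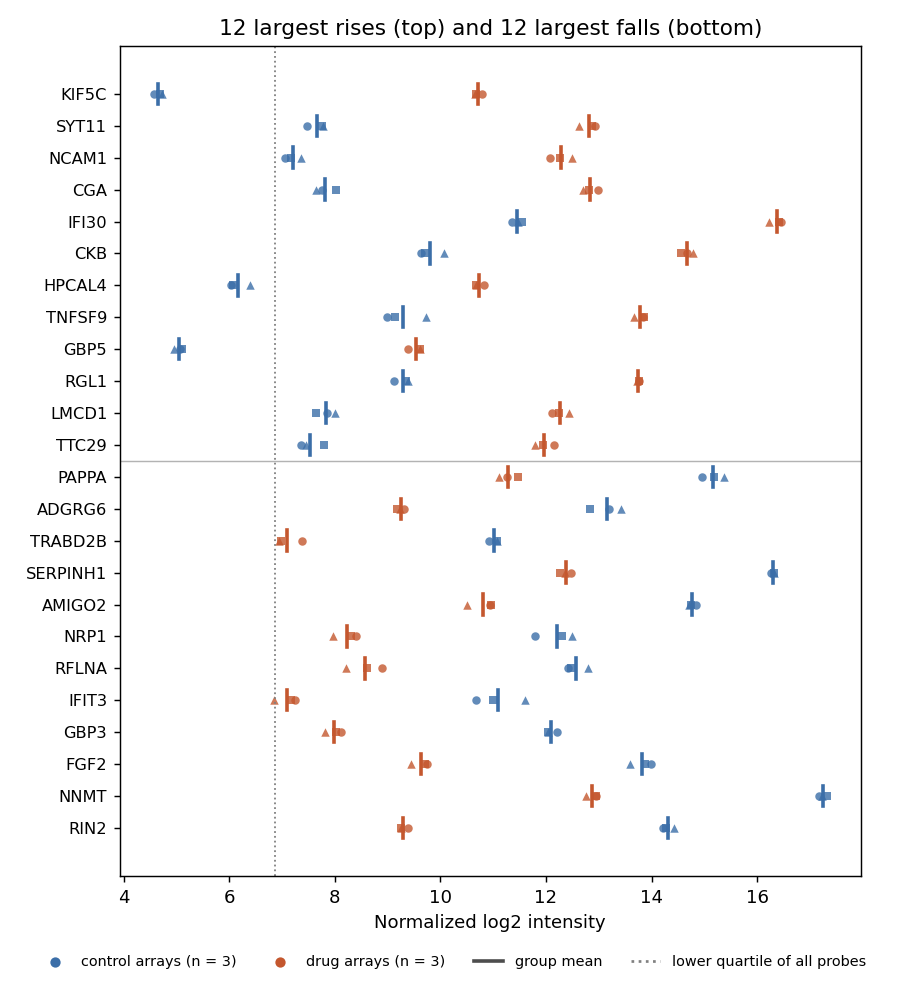
Normalized log2 intensity (x axis) of the 12 genes with the largest rise and the 12 with the largest fall (y axis); each point is an array, blue for control and orange for drug, upright bars are group means of n = 3, and the dotted line is the lower quartile of all probes, 6.86. KIF5C, HPCAL4 and GBP5 lie left of that line in the control flasks, and no gene's groups overlap.

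Over all genes, 6438 of 18336 changed (35.1%), with 3224 higher and 3214 lower in the drug flasks. At least 2-fold changes were seen in 2879 genes, 1470 up and 1409 down. At least 4-fold, 329 genes rose and 235 fell, and at least 8-fold, 93 rose and 39 fell. Of the 93, 25 were dim in the control flasks. Over all probes, 10012 of 31741 changed, 4898 up and 5114 down, among them 1112 of the 6024 probes that name no gene. The 3 drug arrays lay wholly above or below the 3 control arrays for 8622 genes (47.0%, where chance gives 10%), and for 99.97% of the changed genes. Against a minimum log2 change of 0.5, 2820 genes passed.

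Cell cycle genes were lower in the drug flasks. Of the 30 G2/M and mitosis genes, 28 fell and 0 rose, with a median log2 fold change of -1.51. NDC80, a kinetochore protein, changed by -2.46 (SE 0.120), AURKA, a mitotic kinase, by -2.33 (SE 0.176), and BUB1B, a spindle checkpoint kinase, by -2.23 (SE 0.327). Of 29 S-phase and replication genes, 16 fell and 2 rose (18 and 2 adjusted over the list alone), with a median of -0.59. TYMS, which makes thymidylate, changed by -3.0 (SE 0.185), CCNA2, cyclin A, by -2.73 (SE 0.117), and UHRF1, which maintains DNA methylation, by -2.15 (SE 0.213). Of 23 recombination and Fanconi repair genes, 16 fell and 1, RAD51C, rose, with a median of -0.94. RAD51AP1 changed by -2.20 (SE 0.109), the checkpoint kinase CHEK1 by -1.53 (SE 0.126) and RAD54L by -1.53 (SE 0.168). All 3 lists stood apart from the other genes in camera, with adjusted p-values of 5.82e-14 for mitosis, 0.000204 for replication and 6.41e-06 for repair. These calls were lost when camera estimated the correlation between genes, at adjusted p = 0.111, 0.211 and 0.160. At that setting calls were also lost for lists whose estimate lay below the preset, such as cholesterol (-0.0285) and proteasome (-0.0111). The loss is therefore not by itself evidence of correlation between genes. BUB1B was dim with the drug, and its fold of 4.70 became 3.12 with 50 added.

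Lipid synthesis genes were higher. Of 21 genes of cholesterol synthesis and uptake, 16 rose and 2 fell, with a median log2 fold change of 0.82 and a camera adjusted p of 0.00012 (adjusted p = 0.134 with an estimated correlation). IDI1, an isomerase of the mevalonate pathway, rose by 2.96 (SE 0.233), INSIG1, which retains sterol sensors in the endoplasmic reticulum, by 2.69 (SE 0.143), and TM7SF2, a sterol reductase, by 2.09 (SE 0.194). FDPS and ACAT2 were the 2 that fell, by 0.64 and 0.52 on the log2 scale. Of 15 fatty acid synthesis genes, 10 rose and 0 fell (10 and 2 adjusted over the list alone), with a median of 0.84 and an adjusted p of 0.0032 (adjusted p = 0.160 with an estimated correlation). SREBF1, the lipogenic transcription factor, rose by 2.65 (SE 0.182), the acyl-CoA synthetase ACSL3 by 2.32 (SE 0.167) and the desaturase SCD by 1.68 (SE 0.186).

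Of 27 neuroendocrine and neuronal genes, 9 rose, 0 fell and 18 did not pass, with a median log2 fold change of 0.28 against a mean of 0.78 that SYT11 and NCAM1 raise. The list stood apart with an adjusted p of 0.0052 (adjusted p = 0.321 with an estimated correlation). Besides SYT11 and NCAM1, the SNARE protein SNAP25 rose by 2.59 (SE 0.412); it was dim in the control flasks, and its fold of 6.02 became 3.37 with 50 added. The members that rose included the synaptic vesicle proteins SYT1 and SYP, by 1.69 and 1.06, and the neuronal enolase ENO2, by 1.09. The hormone granule marker CHGA, the Notch ligand DLL3 and GRP did not pass, at 0.066, 0.067 and 0.016, and GRP was dim in both groups. CHGB, dim in the control flasks, and SCG2 were among those that rose, by 0.86 and 0.56. Of 24 autophagy and lysosome genes, 10 rose and 3 fell, with a median of 0.28 against a mean of 0.55 and an adjusted p of 0.0369 (adjusted p = 0.312 with an estimated correlation). SESN3, a sestrin, rose by 3.49 (SE 0.127), SQSTM1, the autophagy receptor p62, by 2.47 (SE 0.171), and ATP6V0D1, a subunit of the lysosomal proton pump, by 1.58 (SE 0.146). The fold of SESN3, dim in the control flasks, went from 11.3 to 7.43 with 50 added. The autophagy call was lost in 9 of 21 alternatives (adjusted p from 0.0514 to 0.312), among them without drug 4 (0.0718).

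Of 26 interferon-stimulated genes, 10 fell and 3 rose (12 and 3 adjusted over the list alone), with a median log2 fold change of -0.37 and an adjusted p of 0.0184 (adjusted p = 0.559 with an estimated correlation). Besides IFIT3, IFIT2 changed by -3.49 (SE 0.204) and IFI44 by -3.04 (SE 0.235), the latter dim with the drug, with a fold of 8.22 that became 5.44 with 50 added. The 3 that rose were IRF7, OASL and IRF1, by 1.39, 1.10 and 0.61. The interferon call was lost in 3 of 21 alternatives (adjusted p from 0.0503 to 0.559), among them without control 6 (0.0503) and with the brighter part of the probes alone (0.343). Of 23 splicing factor genes, 12 fell and 0 rose (13 and 0 adjusted over the list alone), with a median of -0.64 and an adjusted p of 4e-04 (adjusted p = 0.160 with an estimated correlation). U2AF2, which recognises the polypyrimidine tract, changed by -1.28 (SE 0.132), RBM39 by -1.16 (SE 0.348) and the SR protein SRSF6 by -1.13 (SE 0.136). RBM39 lost its call in 8 of 19 alternatives (adjusted p from 0.0553 to 0.132). Among them were the fits without control 2, control 5, drug 1 or drug 3 (from 0.0588 to 0.132). Of 30 proteasome genes, 11 fell and 3 rose (12 and 3 adjusted over the list alone), with a median of -0.26 and an adjusted p of 0.0401 (adjusted p = 0.211 with an estimated correlation). The core subunit PSMB2 changed by -0.91 (SE 0.119) and the ATPase PSMC3 by -0.91 (SE 0.158), while the proteasome activator PSME4 rose by 1.03 (SE 0.205). The proteasome call was lost in 9 of 21 alternatives (adjusted p from 0.0506 to 0.211), among them without control 2, drug 1 or drug 3 (from 0.055 to 0.0876).

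**Figure D2:**
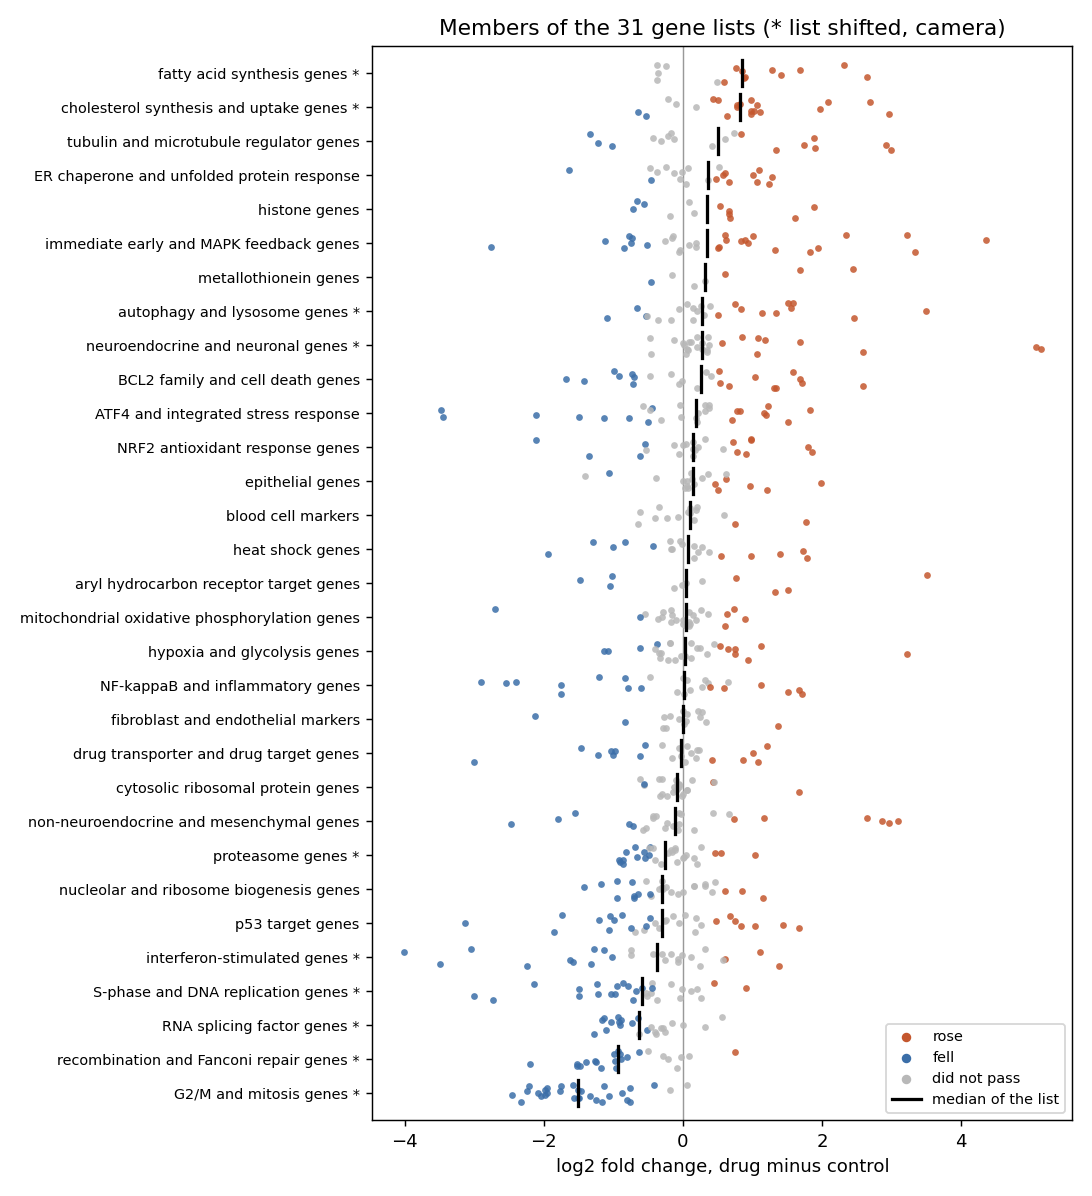
Log2 fold change, drug minus control (x axis), of each measured member of the 31 gene lists (y axis, ordered by median); orange and blue points passed the test, grey points did not, black bars are list medians, and asterisks mark the 10 lists with a camera adjusted p below 0.05. The lowest median is that of the mitosis list, -1.51, and the highest that of the fatty acid list, 0.84.

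The other 21 lists did not stand apart from the remaining genes in the main comparison, although all of them held changed members. Unless a second pair of counts is given, the counts adjusted over the list alone were the same, as they were for 18 of the 31 lists. Of 30 p53 targets, 7 rose and 11 fell (7 and 13 adjusted over the list alone; adjusted p = 0.147). This list was shifted down with the values as deposited (adjusted p = 0.0109) and with median centring (0.017), within a range from 0.0109 to 0.343 over the alternatives that used camera at its preset correlation, so its call depends on the scaling. The death receptor FAS, dim with the drug, changed by -3.13 (SE 0.185), MDM2, the ubiquitin ligase for p53, by -1.85 (SE 0.115) and TP53I3 by -1.74 (SE 0.120), whereas the cell cycle inhibitor CDKN1A rose by 1.67. Of 24 BCL2 family and cell death genes, 10 rose and 7 fell (adjusted p = 0.327). BCL2L11, the death activator BIM, rose by 2.60 (SE 0.158), although 3 of its 5 probes did not pass. BIRC3, an inhibitor of apoptosis, rose by 1.72 (SE 0.139) and cytochrome c, CYCS, by 1.69 (SE 0.206).

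Immediate early and MAPK feedback genes had 15 that rose and 7 that fell of 30 (adjusted p = 0.0813). The orphan nuclear receptors NR4A1 and NR4A3 rose by 4.36 (SE 0.355) and 3.23 (SE 0.156), and FOS by 3.33 (SE 0.136), although 2 of the 3 probes of NR4A3 did not pass. NF-kappaB and inflammatory genes had 6 that rose and 9 that fell of 25 (7 and 10 adjusted over the list alone; adjusted p = 0.551), and the median of 0.022 differed in sign from the mean of -0.26. The cytokine IL1B changed by -2.91 (SE 0.169), NFKB1 by -2.54 (SE 0.112) and the chemokine CCL2 by -2.41 (SE 0.144). In the ATF4 and integrated stress response list, 8 of 28 rose and 8 fell (9 and 10 adjusted over the list alone; adjusted p = 0.984), with a median of 0.19 and a test directed up against a mean of -0.13. NUPR1, a stress-induced chromatin protein, changed by -3.48 (SE 0.159), the transcription factor ATF5 by -3.44 (SE 0.173) and the cystine transporter SLC7A11 by -2.11 (SE 0.128), and by -1.37 on its other probe.

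Of 21 endoplasmic reticulum chaperone and unfolded protein response genes, 9 rose and 2 fell (adjusted p = 0.137). The chaperones HYOU1 and CALR rose by 1.28 (SE 0.116) and 1.24 (SE 0.144), and the transcription factor XBP1 changed by -1.64 (SE 0.145). Of 20 heat shock genes, 5 rose and 5 fell (adjusted p = 0.80). HSPB8 changed by -1.93 (SE 0.165), while HSPA1B and HSPA1A rose by 1.79 (SE 0.141) and 1.73 (SE 0.151), a near-identical pair whose probes cannot be assumed to tell them apart. Of 23 NRF2 targets, 7 rose and 4 fell (8 and 4 adjusted over the list alone; adjusted p = 0.293), with AKR1C3 up by 1.86 (SE 0.129) and SRXN1 by 1.79 (SE 0.160) and SLC7A11, which this list shares, lower. AKR1C3 also has close relatives, and 1 of its 2 probes did not pass. Of 7 metallothionein and zinc genes, 3 rose and 1 fell (adjusted p = 0.142). MT1X rose by 2.45 (SE 0.121), the zinc exporter SLC30A1 by 1.68 (SE 0.150) and MT1B by 0.60 (SE 0.170), but metallothioneins are near-identical copies. MT1B lost its call in 6 of 18 alternatives (adjusted p from 0.0522 to 0.119), among them without any array but control 5.

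Of 18 tubulin and microtubule genes, 7 rose and 3 fell (9 and 4 adjusted over the list alone; adjusted p = 0.145). The neuronal microtubule protein MAP2 rose by 2.99 (SE 0.119), and by 1.32 on its other probe, the neuronal tubulin TUBB3 by 2.93 (SE 0.114) and TUBA4A by 1.90 (SE 0.186). Of 23 drug transporters and targets, 5 rose and 8 fell (adjusted p = 0.589). Besides TYMS, the topoisomerases TOP2A and TOP2B changed by -1.46 (SE 0.110) and -1.22 (SE 0.176). Of 11 aryl hydrocarbon receptor targets, 4 rose and 3 fell (adjusted p = 0.80). CYP1A1 rose by 3.52 (SE 0.217) and the amino acid transporter SLC7A5 by 1.51 (SE 0.176), and ALDH1A3 changed by -1.47 (SE 0.128). Of 12 histone genes, 6 rose and 3 fell (adjusted p = 0.199). H2BC21 rose by 1.89 (SE 0.114) and HIST1H2BG by 1.61 (SE 0.184), and H3C8 changed by -0.72 (SE 0.185). Histone genes share sequence, and HIST1H2BG was dim in both groups with a fold of 3.06 that became 1.84 with 50 added. HIST1H2BG lost its call in 2 of 17 alternatives (adjusted p from 0.0704 to 0.074). H3C8, dim with the drug, lost its call in 6 of 17 alternatives (adjusted p from 0.0511 to 0.274). Among them were the fits without drug 1 or drug 4 (adjusted p = 0.0814 and 0.0601).

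Of 26 non-neuroendocrine and mesenchymal genes, 6 rose and 5 fell (adjusted p = 0.850), and the median of -0.11 and the test pointed down against a mean of 0.16. SNAI1, a repressor of epithelial genes, rose by 3.09 (SE 0.159), the matrix protein THBS1 by 2.97 (SE 0.171) and CCN2, a connective tissue growth factor, by 2.86 (SE 0.233). Of 20 epithelial genes, 6 rose and 1 fell (adjusted p = 0.137). Plakoglobin, JUP, rose by 1.99 (SE 0.162) and E-cadherin, CDH1, dim in the control flasks, by 1.22 (SE 0.141), while the mucin MUC1 changed by -1.07 (SE 0.118). Of 27 hypoxia and glycolysis genes, 7 rose and 4 fell (7 and 5 adjusted over the list alone; adjusted p = 0.80). The aldolase ALDOC rose by 3.22 (SE 0.142) and EGLN3 by 1.13 (SE 0.182), and the kinase PDK1 changed by -1.13 (SE 0.153). EGLN3 was dim in both groups, with a fold of 2.18 that became 1.39 with 50 added. Its call was lost in 3 of 17 alternatives (adjusted p from 0.1 to 0.147).

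Of 28 ribosome biogenesis genes, 3 rose and 9 fell (3 and 12 adjusted over the list alone; adjusted p = 0.102), with UTP20 at -1.43 (SE 0.116), NIP7 at -1.17 (SE 0.174) and BOP1 at 1.15 (SE 0.219). This call depends on the scaling, the model and a single array: the list was shifted down as deposited (adjusted p = 0.00543), with median centring (0.00589), with the title number as a covariate (0.0466) and without control 6 (0.0318), within a range from 0.00543 to 0.222 with camera at its preset correlation. Of 27 ribosomal protein genes, 2 rose and 1 fell (1 and 0 adjusted over the list alone; adjusted p = 0.551). RPLP0 rose by 1.68 (SE 0.236), but its probe was dim in the control flasks, at 6.33. Its fold of 3.20 became 2.36 with 50 added. Whether this probe reads the RPLP0 transcript was not tested. RPL32 rose by 0.44 (SE 0.117) and RPS27L changed by -0.55 (SE 0.142), but many ribosomal protein genes have processed copies. RPL32 lost its call in 8 of 19 alternatives (adjusted p from 0.0565 to 0.217), among them without any array but control 2 (up to 0.103). RPS27L lost its call in 4 of 19 (from 0.0542 to 0.0966), among them without control 6, drug 1 or drug 3 (up to 0.0904). Of 25 oxidative phosphorylation genes, 4 rose and 2 fell (adjusted p = 0.986), with a median of 0.046 against a mean of -0.046 and a test directed down. COX5A changed by -2.70 (SE 0.125), and NDUFA2 and NDUFB3 rose by 0.89 (SE 0.182) and 0.74 (SE 0.139), the latter with 1 of 2 probes that did not pass.

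Markers of other cell types did not stand apart from the remaining genes as lists. Of 16 fibroblast and endothelial markers, 1 rose and 2 fell (adjusted p = 0.850), with a median of 0.0079 against a mean of -0.088 and a test directed down. The collagen COL1A1 changed by -2.12 (SE 0.129), from 14.81 ± 0.12 in the control flasks, POSTN by -0.83 (SE 0.158), and KDR rose by 1.37 (SE 0.142). Of 15 blood cell markers, 2 rose and 0 fell (adjusted p = 0.551), with the haemoglobin gene HBA1 up by 1.77 (SE 0.146) and CD14 by 0.76 (SE 0.113). In fry, which tests for a shift on balance without comparing with other genes, the blood list was called, upwards with a median of 0.10 (adjusted p = 0.00862). HBA1 has a near-identical copy.

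The arrays parted by treatment on the first principal component, which held 64.9% of the variance. Across probes, which are not independent replicates, the correlation between arrays was 0.978 to 0.986 within the control group, 0.985 to 0.990 within the drug group and 0.948 to 0.958 between groups. Drug 3 and drug 4, whose source names carry other cell line numbers, correlated with drug 1 at 0.990 and 0.986. The second component held 14.2% of the variance and spread the arrays within each group, from 49.5 for control 2 to -46.6 for control 6.

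**Figure D3:**
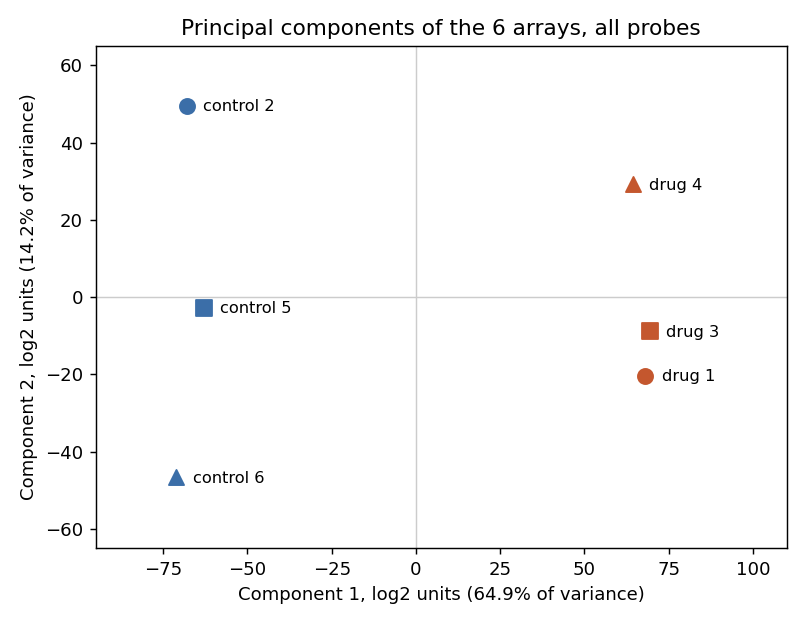
The 6 arrays on components 1 (x axis) and 2 (y axis) of the centred log2 intensities of all probes, with the share of variance on each axis; each point is an array, blue for control and orange for drug. Component 1 parts the groups, from -71.1 to -62.9 for control and from 64.4 to 69.6 for drug, and component 2 spreads arrays within both groups.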

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

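The covariate for array brightness and the fit without the 2 brightest arrays, control 2 and drug 4, were chosen only after the result was seen. No paired analysis was possible because the numbers in the titles run from 1 to 6 over both groups and none is shared. The 4 counts of the comparison stayed within 1.5 times their value in all alternatives but the set tests and the test against a minimum change. Changed genes numbered 4418 at an adjusted p below 0.01, 4955 with the title number as a covariate and 7578 with array weights, and 2820 passed a minimum log2 change of 0.5, where fewer can pass by construction. Without 1 array in turn there were 7637 to 9414 changed probes, 4973 to 6085 changed genes, 2869 to 2951 genes changed at least 2-fold and 9 or 10 shifted lists. Without the 2 brightest arrays 5468 genes changed, 5179 of them among the 6438. In the values as deposited the median of all genes was shifted by 0.205, and 5747 genes changed, 5337 of them among the 6438. The share of changed genes that rose was 50.1%, 52.6% as deposited and 41.6% with median centring, so the balance of rises and falls depends on the scaling. Of 2089 values of the named genes under alternatives, 2051 kept direction and call, 38 kept the direction but no longer passed, and 0 turned.

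None of the 10 shifted lists turned direction in any alternative. With an estimated correlation 0 lists were called. The estimate lay below the preset 0.01 for the cholesterol (-0.0285), fatty acid (-0.00212) and proteasome (-0.0111) lists. Stronger correlation between genes therefore does not account for the loss of those calls. In the simulation, where probes were drawn independently, the adjusted p of the seeded list also went from 1.46e-24 to 0.0246. A loss with an estimated correlation therefore does not show, for any list, that correlation between genes removed the call. No other cause was tested. In fry, 24 lists passed for a shift on balance and 31 for change in either direction, and neither test compares a list with other genes. Calls were gained for p53 targets in 3 of 21 alternatives (as deposited, median centring and fry) and for ribosome biogenesis in 5 (these, the title number as a covariate and the fit without control 6), with medians that stayed negative; the other gains were with fry alone. Lists whose test turned direction were not called in the main comparison or in the alternative, and the cause was not tested. Camera sets a list against the other genes, so the sign of a list median need not be that of the test. The median of all genes was 0.00753 in the main comparison and 0.205 as deposited. The medians of these lists as deposited were 0.14 for ATF4, 0.075 for heat shock, -0.040 for hypoxia, 0.28 for aryl hydrocarbon receptor targets and 0.28 for fibroblast and endothelial markers. With median centring, where the median of all genes was 0.074, they were 0.010 for ATF4, -0.056 for heat shock, -0.17 for hypoxia and 0.15 for fibroblast and endothelial markers. The last list also turned with cyclic loess, at 0.051. With the brighter part of the probes ATF4 had 0.18 and hypoxia -0.026, with fry ATF4 had 0.19 and non-neuroendocrine genes -0.11, and without the 2 brightest arrays oxidative phosphorylation had 0.0025. Without 1 array in turn the medians ran from 0.12 to 0.23 for ATF4, from -0.21 to -0.12 for non-neuroendocrine genes and from -0.0030 to 0.090 for oxidative phosphorylation.

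The mean correlation within and between groups and the share of the first component were 0.979, 0.878 and 79.2% with the brighter part of the probes, and 0.975, 0.940 and 68.3% as deposited; the cause was not tested. Without 1 array in turn they ran from 0.982 to 0.987, from 0.951 to 0.953 and from 63.2% to 71.1%. Signal over background limits what can be said of dim genes: of the 1470 genes that rose at least 2-fold, 224 were dim in the control flasks, and of the 1409 that fell as much, 115 were dim with the drug.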

Other observations

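The 6 gene groups described first, the values far from their group, the count of genes that adding 50 could affect, and the tests of background in genes dim or not dim, of other cell lines in drug 3 and drug 4 and of array brightness were chosen only after the result was seen. Of 8 ligands of the NKG2D receptor, which natural killer cells read on stressed cells, 4 rose and 0 fell. ULBP2 rose by 3.86 (SE 0.175) on the log2 scale, RAET1G by 3.32 (SE 0.161), MICB by 2.42 (SE 0.164) and MICA by 2.41 (SE 0.135). ULBP1 (0.63), ULBP3 (0.40), RAET1L (0.022) and RAET1E (-0.083) did not pass. Whether the probes tell these related genes apart was not tested. MICA also sits on the list, given below, of genes taken to rise under histone deacetylase inhibitors. Among 7 guanylate-binding proteins, GBP5 rose by 4.49 and GBP3 changed by -4.11, and the other 5 did not pass. Of 8 measured genes of the placenta, CGA, PEG10 (3.93), PGF (2.45, dim in the control flasks) and TFPI2 (1.35) rose, and PAPPA and ERVW-1 (-0.66) fell.

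Of 14 genes of the Hippo pathway and its targets, 5 rose and 3 fell. The coactivator YAP1 changed by -2.48 (SE 0.115), from 14.23 ± 0.037 in the control flasks, and its relative WWTR1 rose by 1.17 (SE 0.123). Of the targets, CCN2 rose by 2.86 (SE 0.233) and ANKRD1 by 2.64 (SE 0.172), while CCN1 (0.67, adjusted p = 0.141) did not pass. Among 9 measured transcription factors of lineage or subtype, YAP1 fell and the other 8 did not pass. These included INSM1 (0.35), REST (-0.031), MYC (-0.051) and NEUROD1, which was dim in both groups. Whether the levels of these genes in the control flasks are those of NCI-H446 was not tested. Of 11 histone deacetylase genes, HDAC3 (1.31), HDAC5 (0.96, dim in the control flasks), HDAC1 (0.85), HDAC2 (0.71) and HDAC11 (0.60) rose, and HDAC7 (-2.28) and HDAC9 (-2.24) fell.

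The 329 genes that rose at least 4-fold included KIF5C, SYT11, NCAM1 and CGA, which raised the idea that the drug may act as a histone deacetylase inhibitor. A list of 20 genes taken to rise under such inhibitors had a median log2 fold change of 1.06, at percentile 100 of 10000 random lists matched on level, with 12 that rose and 1, RECK, that fell, but the idea came after the largest changes and part of the lists had been seen, TUBB3 sits on both this and the tubulin list, and the 6 genes taken to fall had a median of -0.16 at percentile 28.7. Background subtraction of dim probes stays open. For the 257 that were not dim in the control flasks, the smallest rise in mean deposited intensity was 409.6. The lower quartiles of the arrays differed by at most 46.8. A 4-fold rise from above the lower quartile passes that difference by the choice of genes, so this comparison could hardly fail. It shows only that these rises were larger than the differences in lower quartile. With 50 added, 99.1% of the 329 and 95.8% of the 72 dim ones stayed at least 2-fold higher. A 4-fold rise could fall below that for only 4 of the 329, of which 1 stayed. Another cell line in the drug flasks stays open too: 0.694% of 144 overlapping windows of 100 neighbouring genes had an absolute median above 0.3, the same as the highest of 100 shuffled gene orders, and the largest, 0.307, lay below the shuffled highest of 0.392, but the spread of the window medians, 0.0944, lay above the shuffled highest of 0.0885, the limit of 0.3 was assumed, and no table measures what another line would give. Histone deacetylase inhibition stays a hypothesis, since the drug is unnamed, other drug classes were not tested, and dose and time are unknown.

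The source names of drug 3 and drug 4 carry other cell line numbers than that of drug 1. It was assumed that, had these flasks held other lines, the drug arrays would correlate less with each other than the control arrays do. The lowest correlation between drug arrays was 0.985, across probes, and the lowest between control arrays was 0.978. Under that assumption the values argue against drug 3 and drug 4 holding other lines than drug 1. The correlation that another line would give was not measured. The comparison cannot tell whether all 3 drug flasks share another line. The numbers in the source names may come from a counter in the sheet, which was not tested.

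The second component, which spreads the arrays within groups, may follow array brightness. The log2 scale factor of an array and its position on that component had a Pearson r of -0.941 (exact permutation p = 0.00556, two-sided) and a Spearman rho of -0.943 (exact permutation p = 0.0167) over 6 arrays, the only relation computed. Without control 2 and drug 4, the arrays farthest from the median, r was -0.637, so the relation rests on those arrays. Both groups hold bright and dim arrays, and with the scale factor as a covariate 7162 genes changed, 6347 of them among the 6438. No biological explanation was tested for this component.

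The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For changed probes, changed genes, genes changed at least 2-fold and shifted lists alike, 1 of the 10 splits, the real one, gave a result as large. The real split gave 10012 probes, 6438 genes, 2879 genes and 10 lists, and the highest of the others 0, 0, 0 and 7. Every other split mixes drug and control arrays, so the difference between treatments adds to the spread within its groups. Their counts of 0 are therefore no measure of what chance alone would give.

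Single values lay far from their group on each array. Of 190446 values, 126 were more than 3 log2 units from the median of their group, 47 above and 79 below, on 109 probes that include 48 genes and 0 of the 111 named ones. DHRS2 had 2.47, 10.5 and 10.43 on control 2, 5 and 6 and 15.34, 15.54 and 0.93 on drug 1, 3 and 4 (log2 fold change 2.80, SE 4.14, adjusted p = 0.695). CSF3 had 14.55, 16.28 and 2.47 on the control arrays and 16.64, 16.66 and 15.92 on the drug arrays (5.31, SE 3.26, adjusted p = 0.292).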
